A study of Mus musculus with 16 samples.

How the data were processed

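RNA of mouse neural crest stem cells was measured on 16 Affymetrix arrays in 4 groups of 4. The groups are unprimed cells and cells primed towards glia, neurons or mesenchyme, and both the group and the replicate number come from the sample titles and the cell type label. Per the labels' protocols, biotinylated cRNA was made from 2 ug of total RNA with a one-cycle labelling kit. The growth factors used for priming and the length of the exposure are not given in the sources used here. The labels do not say whether replicates came from separate cultures or embryos, so p-values measure only the spread between these samples, which may in part be technical.

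The deposited table holds 1 intensity per probe set and array. The authors made these values with RMA, which subtracts background, equalises the distributions of the arrays and summarises the probes of a probe set, per the submitters' processing notes, which give no version. The deposited intensities run from 1.49 to 31600 and are therefore on a linear scale, although RMA commonly returns log2 values, on which the planned test was based. The log2 of each value was taken here with no offset, and no further normalization was applied. Scanner files were not used here. For arrays there is no read depth, and the number of arrays limits the precision. With genes ranked by mean into 4 equal bins, the median residual SD was 0.257 on the log2 scale in the dimmest bin, against 0.713 and 0.523 in the brightest ones. Signal over background was not measured here, so the size of a change over a dim baseline is rough.

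Of 45101 probe sets, 34958 carried a single gene symbol in the platform annotation, 932 carried several and 9211 were not listed there. Probe sets with several symbols or none were left out of the gene tests. Symbols were updated through Entrez identifiers to the GRCm38.p6 gene table, which matched 96.8% of them, and no coordinates were used. For each of 18194 genes the probe set with the highest mean over all arrays was kept, and 9012 genes had more than 1 to choose from.

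A group-means model over all 16 arrays was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that the 4 groups shared an estimate of the spread. Each primed group, and the mean of the 3, was set against the unprimed arrays, and the primed groups were set against each other, giving 7 comparisons. Tests were two-sided, and p-values were adjusted over all genes by the Benjamini-Hochberg method, with genes called at an adjusted p under 0.05. Unless another test is named, adjusted p-values of genes are from this model. A total of 36 gene lists were written before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They cover neural crest and lineage markers, signalling responses, cell cycle, metabolism, ribosomes, stress and the markers of other embryonic cell types. Camera asks whether a list moved relative to all other genes. Each list was also tested with camera at an estimated correlation and with fry, which asks whether its genes moved on balance in 1 direction. The ribosomal protein list has 42 measured members, because many of its probe sets match several genes.

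Named genes follow a rule set before the data were examined. In each comparison of a primed group with unprimed arrays it takes the 6 largest rises and the 6 largest falls among called genes whose arrays did not overlap between the groups, up to 4 called members of each lineage list, and up to 2 called members, in the direction of the list's shift, of each other list that camera called or that marks another cell type. It adds Yy1 and Sox10 always, the 6 largest changes restricted to a lineage or shared by all, and the 3 largest differences each way between primed groups. Other genes are named as examples of their list and were chosen after their values were seen.

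The scripts were tested on simulated data drawn from the gene means and residual SDs of the 18194 genes for the comparison of glia-primed with unprimed arrays. Of 50 changed genes per size, all drawn from genes brighter than the median gene, 10 were called at a 2-fold change, 31 at 4-fold, 45 at 8-fold and 50 at 16-fold, and 10 of 147 calls were false. The noise was independent between genes, so neither the recovery of dim genes nor the effect of correlated genes on false calls was tested. Changes near 2-fold in such brighter genes were therefore mostly missed in a design of this size.

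Before the data were examined, the alternatives fixed were the replicate number as a block, 3 other scalings of the arrays, filters on dim genes, other choices of probe set, other settings of eBayes, array weights, a test against a 1.2-fold change, fits of only the groups compared, and leaving out each array. Added after seeing the data were log2 of the value plus 16, the Xist level as a covariate, the 3' to 5' ratio of the Gapdh control probe sets as a covariate, and list tests between primed groups. The housekeeping genes fixed for centring numbered 10, of which 7 were measured. The fixed set includes Gapdh and Pgk1, which are also on the glycolysis list, so this centring is not independent of that list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.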

Results

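Neural crest stem cells are multipotent embryonic cells that give rise to peripheral glia, autonomic neurons and mesenchymal tissues. Expression was measured on 16 arrays, with 4 of unprimed cells and 4 each of cells primed towards glia, autonomic neurons or mesenchyme. The series set out to compare migratory crest cells before and after priming by instructive growth factors. Median intensities per array lay between 8.26 and 8.85 on the linear scale (3.05 to 3.15 on the log2 scale). Correlations between arrays were 0.899 to 0.957 within groups and 0.904 to 0.958 between groups. No pair of arrays held identical values. The first principal component took 14.4% of the variance and set glia-primed arrays (19.4 to 46.5) and neuron-primed replicates 2 to 4 (28.9 to 57.3) apart from unprimed arrays (-49.65 to -21.18) and mesenchyme-primed arrays (-24.8 to -8.02). Neuron-primed replicate 1 lay at -39.7, among the unprimed arrays. By the Gapdh control, array quality moved with priming, since the 3' to 5' log2 ratio of its probe sets was 2.35 ± 0.187 (SD, n = 4) in unprimed, 2.95 ± 0.391 in glia-primed, 2.85 ± 0.242 in neuron-primed and 2.96 ± 0.222 in mesenchyme-primed arrays. The beta-actin ratio was -0.531 ± 0.158, -0.17 ± 0.0784, -0.498 ± 0.284 and -0.282 ± 0.15 in these groups, so by this control neuron-primed arrays lay close to unprimed ones. Xist, which is transcribed from the inactive X chromosome, ranged from 6.39 to 10.5 on the log2 scale in unprimed and from 2.61 to 5.34 in glia-primed arrays, and spanned 3.15 to 10.6 in neuron-primed and 2.68 to 11.2 in mesenchyme-primed arrays.

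The comparison of glia-primed with unprimed cells asked what the glial growth factor condition changes. Glia-primed cells had lower RNA of the cholesterol pathway and higher RNA of TGF-beta and BMP response genes. Pmepa1, a TGF-beta-induced inhibitor of SMAD signalling, rose from 3.78 ± 1.2 to 9.18 ± 0.37 (log2 intensity, SD, n = 4), a log2 change of 5.40 (SE 0.54, limma adjusted p = 0.000207). Spsb1 rose from 3.77 ± 1 to 8.77 ± 0.39 (adjusted p = 0.000142). Slc2a3, a neuronal-type glucose transporter, fell from 9.69 ± 0.52 to 5.65 ± 1.2 (log2 change -4.04, SE 0.56, adjusted p = 0.00457). Its change was -2.46 with cross-matching probe sets left out. Mvd, an enzyme of the mevalonate pathway, fell from 8.64 ± 0.11 to 5.28 ± 0.34 (log2 change -3.37, SE 0.24, adjusted p = 1.75e-05).

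Among 20 measured genes of cholesterol synthesis, 0 rose, 13 fell and 7 did not pass, and 20 fell when adjusted over the list alone. Their median log2 change was -2.30 (camera adjusted p = 7.92e-44, and adjusted p = 0.000214 with an estimated correlation). Dhcr7, which makes cholesterol from its last precursor, changed by -3.50 (SE 0.52, adjusted p = 0.00731) and Nsdhl by -3.30 (SE 0.31, adjusted p = 0.000178). Insig1, which retains the SREBP regulators in the endoplasmic reticulum, changed by -2.77 (adjusted p = 0.0011) and Sqle, the squalene epoxidase, by -2.19 (adjusted p = 0.000178). Srebf2, which encodes a regulator of the pathway, did not pass (log2 change -1.50, adjusted p = 0.275).

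Glycolysis genes were lower as a list (median -0.76, camera adjusted p = 1.37e-12, and adjusted p = 0.011 with an estimated correlation). Of 19 members 0 rose, 3 fell and 16 did not pass, and 12 fell when adjusted over the list alone, with Pfkl at -1.76 (SE 0.33, adjusted p = 0.0342) and Tpi1 at -1.54 (adjusted p = 0.00392). DNA replication genes were lower (median -0.59, camera adjusted p = 2.38e-11, and adjusted p = 0.0191 with an estimated correlation), and of 31 members 1 fell, Gins2 (log2 change -1.41, SE 0.27, adjusted p = 0.0364), with 6 lower when adjusted over the list alone. Mitotic genes had a median of -0.38 (camera adjusted p = 0.000212), and 1 of 33 fell, Anln, a contractile-ring protein (log2 change -1.32, SE 0.27, adjusted p = 0.0452), but the list's call was lost at adjusted p = 0.129 with an estimated correlation, while fry gave an adjusted p of 0.037. Hypoxia-response genes had a median of -0.63 (camera adjusted p = 0.00015, and adjusted p = 0.0633 with an estimated correlation), and 1 of 21 fell, Ak4 (log2 change -1.42, SE 0.26, adjusted p = 0.0308), with 1 higher and 7 lower when adjusted over the list alone. The arrays with these lower lists also had the higher Gapdh ratio of 2.95 and the lower Xist level.

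TGF-beta response genes were higher as a list (median 0.88, camera adjusted p = 1.92e-06, and adjusted p = 0.011 with an estimated correlation), with 1 of 19 risen, 0 fallen and 18 not passed, and 5 risen when adjusted over the list alone. BMP response genes were higher (median 0.45, camera adjusted p = 6.12e-06, and adjusted p = 0.011 with an estimated correlation), with 2 of 20 risen and 18 not passed, and 6 risen and 1 fallen when adjusted over the list alone. The 2 were Dlx2, a homeobox transcription factor (log2 change 4.57, SE 0.93, adjusted p = 0.0452), and Id3, an inhibitor of basic helix-loop-helix factors (log2 change 1.28, SE 0.24, adjusted p = 0.0335). Smooth muscle genes (median 0.63, camera adjusted p = 7.63e-05) had 0 of 26 passed and 6 higher and 1 lower when adjusted over the list alone, and the call was lost at adjusted p = 0.317 with an estimated correlation. Matrix genes (median 0.43, camera adjusted p = 7.63e-05) had 1 of 33 risen, the collagen Col1a2 (log2 change 2.05, SE 0.38, adjusted p = 0.0335), with 4 higher when adjusted over the list alone, and adjusted p = 0.417 with an estimated correlation.

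Glia and Schwann cell markers did not move as a list (camera adjusted p = 0.83, median -0.04). Of 30 members, 1 rose, Cryab, a small heat shock protein (log2 change 4.46, SE 0.81, adjusted p = 0.0335). In neuron-primed cells the change of Cryab was 3.84 and did not pass (adjusted p = 0.0586). Its difference between glia- and neuron-primed cells was 0.61 (adjusted p = 0.96), so its rise was not shown to be particular to glia priming. Ngfr, the low-affinity neurotrophin receptor, fell (log2 change -1.87, SE 0.39, adjusted p = 0.0479), and 28 did not pass, with 2 higher and 2 lower when adjusted over the list alone. Crest progenitor genes did not move as a list either (camera adjusted p = 0.677), with 0 risen, 1 fallen and 26 not passed, and 4 higher and 4 lower when adjusted over the list alone. Sox10, a crest and glial transcription factor, had a log2 change of -0.26 (adjusted p = 0.95), and Yy1, a zinc finger regulator, of 0.14 (adjusted p = 0.875). The other Sox10 probe sets gave 0.45 and 0.66, so the sign of its change is not settled. Among the largest changes were rises of Rassf4 (4.24, SE 0.71, adjusted p = 0.0185) and the amino acid transporter Slc6a15 (4.19, SE 0.54, adjusted p = 0.00311), and falls of Rdh10, which makes retinal for retinoic acid synthesis (-3.89, SE 0.41, adjusted p = 0.000311), and Nr6a1, an orphan nuclear receptor (-3.25, SE 0.51, adjusted p = 0.0114). Unprimed log2 levels of Rassf4 (2.22), Slc6a15 (2.77), Cpm (2.10) and Sfxn3 (2.92) lay below the array medians, that of Gpr17 (3.05) at them and that of Vgf (3.54) above them. Those of Pmepa1 (3.78), Spsb1 (3.77), Cryab (4.03) and Dlx2 (5.08) also lay above them, but unprimed replicate 4 was below them at 2.71, 2.85, 1.81 and 2.41. None of these was shown to exceed background, so the sizes of these genes' rises, in each comparison that names them, are rough. Dimmer Pmepa1 probe sets (means 4.15 and 2.69) rose less, by 1.55 and 0.45 in glia-, 1.70 and 0.25 in neuron- and 0.83 and 0.32 in mesenchyme-primed arrays. Col2a1, a cartilage collagen, rose by 2.10 (SE 0.40, adjusted p = 0.0342), while cartilage and bone markers as a list gave a camera adjusted p of 0.83.

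In all, 93 of 18194 genes changed, 34 higher and 59 lower, of which 34 and 57 were at least 2-fold, and 1803 had an unadjusted p under 0.05. The 8 arrays did not overlap for 1306 genes (7.18%, against 2.86% by chance). The count was 37, 42, 50 and 25 without unprimed replicates 1 to 4, 49, 42, 42 and 48 without glia-primed replicates 1 to 4, 168 without neuron-primed replicate 1, which enters only the spread, and 59 without mesenchyme-primed replicate 1. With covariates added after seeing the data it was 26 with the Xist level (19 of the 93 among them) and 30 with the Gapdh ratio (19 of the 93). Under centring on housekeeping genes, which moved the median of all genes by 0.33, the split was 67 higher and 21 lower, and under cyclic loess it was 39 and 36. The calls of Dlx2 (adjusted p of 0.0152 to 0.17 over the alternatives), Ngfr (0.0207 to 0.315), Anln (0.0242 to 0.742) and Gins2 (0.0188 to 0.352) were lost without any of 13, 14, 12 and 10 single arrays. Col2a1 (0.0158 to 0.183) was lost without any of 8, Col1a2 (0.00867 to 0.209) and Pfkl (0.0171 to 0.257) of 7, and Cryab (0.00351 to 0.126), Rassf4 (0.000813 to 0.18), Id3 (0.00588 to 0.161) and Ak4 (0.012 to 0.14) of 6.

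**Figure D1:**
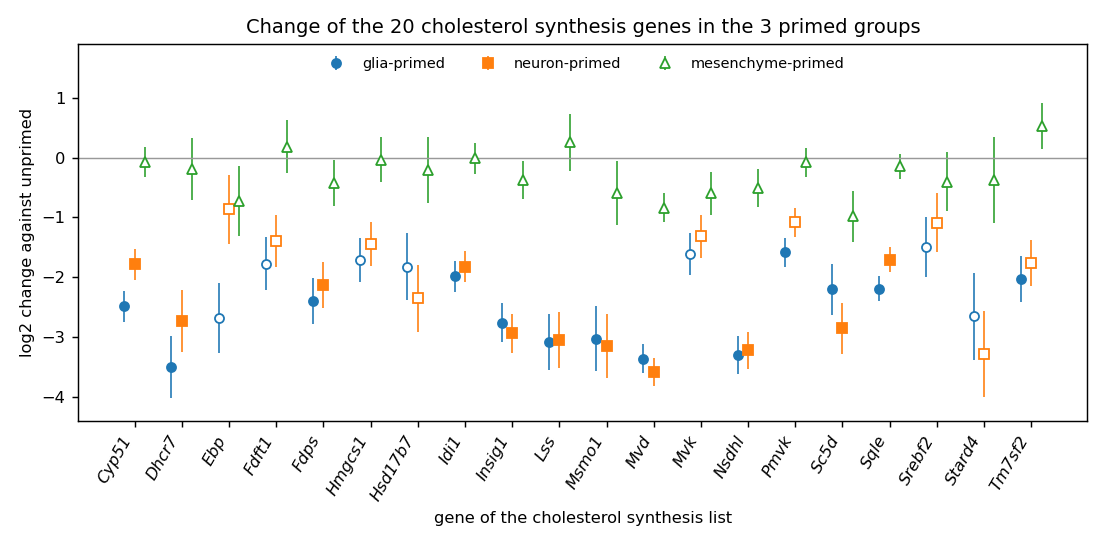
Log2 change against unprimed cells of 20 cholesterol synthesis genes in the 3 primed groups, with bars of 1 SE and filled points for an adjusted p under 0.05. In glia-primed cells 13 genes passed and in neuron-primed cells 11, against 0 in mesenchyme-primed cells, where the median was -0.29.

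The comparison of neuron-primed with unprimed cells asked the same of the autonomic neuron condition. Pmepa1 rose to 9.03 ± 0.72 (log2 change 5.24, adjusted p = 0.000447) and Vgf, a secreted neuropeptide precursor, rose to 8.35 ± 2 (log2 change 4.82, SE 0.83, adjusted p = 0.0197). Mef2c, a transcription factor active in crest and muscle, fell from 7.19 ± 0.68 to 3.21 ± 0.2 (log2 change -3.99, SE 0.42, adjusted p = 0.000506). Ngfr fell by 2.75 on the log2 scale (SE 0.39, adjusted p = 0.00554) and Mycn, a proto-oncogene of proliferating progenitors, by 2.07 (SE 0.30, adjusted p = 0.00719). Other large rises were Spsb1 (3.96, adjusted p = 0.000787), Sfxn3 (3.81, SE 0.60, adjusted p = 0.0109), the carboxypeptidase Cpm (3.81, SE 0.39, adjusted p = 0.000447) and Sipa1l2 (2.69, SE 0.35, adjusted p = 0.00283). Other large falls were the ceramide synthase Cers4 (-4.32, SE 0.67, adjusted p = 0.00977), Bnip3, a hypoxia-induced mitophagy receptor (-4.09, SE 0.79, adjusted p = 0.0333), and Cfap410 (-3.56, SE 0.55, adjusted p = 0.00978). Cfap410 rests on a cross-matching probe set, and its change was 0.04 with such probe sets left out.

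Of 20 cholesterol synthesis genes 0 rose, 11 fell and 9 did not pass, and 19 fell when adjusted over the list alone (median -1.97, camera adjusted p = 6.15e-39, and adjusted p = 0.000389 with an estimated correlation). Mvd changed by -3.59 (SE 0.24, adjusted p = 7.39e-06), Nsdhl by -3.23 (adjusted p = 0.000447) and Insig1 by -2.94 (adjusted p = 0.000787). Glycolysis genes had a median of -0.74 (camera adjusted p = 1.06e-13, and adjusted p = 0.00728 with an estimated correlation), with 2 of 19 fallen, Pfkl (-2.25, adjusted p = 0.00719) and Tpi1 (-1.10, adjusted p = 0.0327), and 11 fallen when adjusted over the list alone. DNA replication genes had a median of -0.52 (camera adjusted p = 4.94e-10, and adjusted p = 0.0366 with an estimated correlation), with 2 of 31 fallen, Tk1 (-1.96, SE 0.37, adjusted p = 0.0333) and Gins2 (-1.37, adjusted p = 0.043), and 8 fallen when adjusted over the list alone. TGF-beta response genes had a median of 1.01 (camera adjusted p = 1.84e-08, and adjusted p = 0.00676 with an estimated correlation), with 1 of 19 risen and 4 when adjusted over the list alone.

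Smooth muscle genes were higher as a list (median 0.45, camera adjusted p = 0.000187), with 0 of 26 passed and 5 higher when adjusted over the list alone, and adjusted p = 0.29 with an estimated correlation. Matrix genes were higher (median 0.49, camera adjusted p = 0.00136), with 0 of 33 passed and 4 higher when adjusted over the list alone, and adjusted p = 0.541 with an estimated correlation. Under centring on housekeeping genes, which raised the median of all genes, their median was 0.925 and camera did not call the list (adjusted p = 0.268). This centring shifts all genes of an array alike, so the list's log2 change relative to other genes was as before. Neuron-primed replicate 1 was the lowest of its group in both lists, at a mean of 5.60 against 6.56 to 7.22 and of 4.32 against 5.16 to 5.70. BMP response genes were higher (median 0.38, camera adjusted p = 0.00741), with 0 of 20 passed and 0 when adjusted over the list alone, and adjusted p = 0.0992 with an estimated correlation. With the same centring on housekeeping genes their median was 0.824 and camera did not call the list (adjusted p = 0.0638). Its log2 change relative to other genes was again as before.

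Autonomic neuron genes were higher as a list (median 0.22, camera adjusted p = 0.0206), with 0 of 25 passed and 1 higher when adjusted over the list alone, and adjusted p = 0.169 with an estimated correlation. The adjusted p was 0.218 without neuron-primed replicate 1 (median 0.151) and 0.0595 without unprimed replicate 3 (median 0.19). It was 0.079 under cyclic loess (median 0.188) and 0.0728 under housekeeping centring (median 0.661, with all genes moved by 0.44). General neuronal genes were higher (median 0.30, camera adjusted p = 0.0202), with 0 of 30 passed and 4 higher when adjusted over the list alone, and adjusted p = 0.286 with an estimated correlation. Without neuron-primed replicate 1 the median was 0.077 (adjusted p = 0.492), and the adjusted p was 0.067 without unprimed replicate 2 (median 0.264) and 0.301 under housekeeping centring (median 0.735). Crest progenitor genes were lower (median -0.42, camera adjusted p = 0.0326), with 2 of 27 fallen, 1 higher and 2 lower when adjusted over the list alone, and adjusted p = 0.286 with an estimated correlation. Their median was -0.036 without neuron-primed replicate 1 (adjusted p = 0.236), the adjusted p was 0.116, 0.067 and 0.129 without unprimed replicates 1 to 3 and 0.108 under cyclic loess. Centring on housekeeping genes, which moved all genes by 0.44, put the median at 0.017, still below other genes (camera adjusted p = 0.000479). Glia and Schwann cell markers did not move as a list (camera adjusted p = 0.28), and 2 of 30 fell, Ngfr and Cnp, a myelin enzyme (-2.91, SE 0.59, adjusted p = 0.0465). Cnp also rests on a cross-matching probe set, and its change was -0.52 with such probe sets left out (adjusted p = 0.652). Of its other probe sets, of nearly equal mean (4.99 and 4.96), the brighter gave this value and the other gave -1.97. Hypoxia-response genes had a median of -0.30 (camera adjusted p = 0.000187, and adjusted p = 0.0717 with an estimated correlation) with 2 of 21 fallen, Bnip3 and Ak4 (-1.45, adjusted p = 0.0252, and 0.0583 without cross-matching probe sets), and 6 fallen when adjusted over the list alone, and with all genes moved by 0.44 under housekeeping centring the median was 0.14, still below other genes (camera adjusted p = 5.35e-06). Stress response genes were higher (median 0.46, camera adjusted p = 0.000853), with 0 of 22 passed and 4 higher when adjusted over the list alone, and adjusted p = 0.0897 with an estimated correlation. Macrophage markers were also higher as a list (median 0.21, camera adjusted p = 0.0206), with 0 of 18 passed and adjusted p = 0.299 with an estimated correlation, and the adjusted p was 0.067, 0.0566 and 0.075 without unprimed replicate 2 and neuron-primed replicates 1 and 4 (medians 0.173, 0.243 and 0.095), and 0.0898 and 0.0569 under cyclic loess and housekeeping centring (medians 0.173 and 0.651). Col2a1 rose by 2.43 (SE 0.40, adjusted p = 0.0149), and Noc2l, of ribosome biogenesis, fell by 0.99 (SE 0.18, adjusted p = 0.0294). A dimmer Noc2l probe set (mean 4.16 against 9.58) gave a change of 0.40. Sox10 had a log2 change of -0.63 (adjusted p = 0.868), with replicate 1 at 4.30 and the others of its group at 8.07 to 8.27, and Yy1 of -0.58 (adjusted p = 0.283).

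In all, 79 genes changed, 24 higher and 55 lower, with 24 and 53 at least 2-fold, and 1783 at an unadjusted p under 0.05. No overlap between the arrays was seen for 1006 genes (5.53%, against 2.86% by chance). The count was 37, 43 and 31 without unprimed replicates 1, 2 and 4, and 237, 43, 38 and 36 without neuron-primed replicates 1 to 4. It was 33 with the Gapdh ratio as a covariate (26 of the 79 among them) and 17 with only these groups fitted. Under centring on housekeeping genes, which moved the median of all genes by 0.44, the split was 81 higher and 17 lower, and under cyclic loess it was 30 and 44. The calls of Cnp (adjusted p of 0.0133 to 0.652 over the alternatives) and Gins2 (0.0174 to 0.289) were lost without any of 13 single arrays, Vat1l (0.00518 to 0.109) of 9 and Bnip3 (0.00505 to 0.121) of 8. Tk1 (0.0215 to 0.135) and Tpi1 (0.00325 to 0.182) were lost without any of 7, Noc2l (0.0155 to 0.859) and Ak4 (0.0132 to 0.123) of 6, Vgf (0.000746 to 0.144) of 5 and Col2a1 (0.00452 to 0.0993) of 2.

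The comparison of mesenchyme-primed with unprimed cells asked the same of the mesenchymal condition. Mesenchyme-primed cells differed from unprimed cells in 4 genes, with Pmepa1 higher at 8.09 ± 0.73 (log2 change 4.30, adjusted p = 0.0203). Sipa1l2 rose by 2.35 (adjusted p = 0.0465), and Gpr17, a receptor of the oligodendrocyte lineage, rose from 3.05 ± 0.068 to 5.07 ± 0.74 (log2 change 2.02, SE 0.30, adjusted p = 0.0465). Gins2, a subunit of the replication helicase, changed by -1.81 (SE 0.27, adjusted p = 0.0465). Spsb1 did not pass (log2 change 2.67, adjusted p = 0.0723), nor did Sox10 (0.99, adjusted p = 0.809) or Yy1 (-0.00, adjusted p = 0.999).

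Matrix genes were higher as a list (median 0.48, camera adjusted p = 0.00095), with 0 of 33 passed and 1 higher when adjusted over the list alone, and adjusted p = 0.486 with an estimated correlation. Without mesenchyme-primed replicate 3 the median was 0.024 (adjusted p = 0.399). Macrophage markers were higher as a list (median 0.16, camera adjusted p = 0.00251), with 0 of 18 passed and 0 when adjusted over the list alone, and adjusted p = 0.225 with an estimated correlation. They averaged 3.43 in replicate 3 against 2.49 to 2.81 in the others of its group, and without it the median was 0.085 (adjusted p = 0.176). Endothelial markers were lower (median -0.27, camera adjusted p = 0.0392), with 0 of 15 passed and adjusted p = 0.486 with an estimated correlation. Their adjusted p was 0.269 without unprimed replicate 3 (median -0.225), 0.0666, 0.101 and 0.0967 without mesenchyme-primed replicates 1, 3 and 4 (medians -0.229, -0.268 and -0.306), and 0.0868 under housekeeping centring (median -0.193). TGF-beta response genes had a median of 0.59 (camera adjusted p = 0.0012), with 1 of 19 risen, also when adjusted over the list alone, and adjusted p = 0.194 with an estimated correlation. Hypoxia-response genes were higher (median 0.46, camera adjusted p = 2.11e-05), with 0 of 21 passed and 1 higher when adjusted over the list alone, and adjusted p = 0.178 with an estimated correlation. DNA replication genes were lower (median -0.30, camera adjusted p = 2.11e-05), with 1 of 31 fallen and 3 when adjusted over the list alone, and adjusted p = 0.198 with an estimated correlation. Ribosomal protein genes had a median of -0.18 (camera adjusted p = 1.58e-06) and mitochondrial ribosome genes of -0.36 (camera adjusted p = 1.12e-05), with adjusted p = 0.198 and 0.194 with an estimated correlation. Smooth muscle genes (camera adjusted p = 0.0745), cholesterol synthesis genes (median -0.29, camera adjusted p = 0.0509) and cartilage and bone markers (camera adjusted p = 0.24) did not pass. Camera with a preset correlation called 12 lists, but 0 with an estimated correlation, where 7 had an unadjusted p under 0.05, and fry called 1. These arrays had the Gapdh ratio of 2.96 against 2.35 in unprimed arrays.

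The 4 calls stood beside 1401 genes at an unadjusted p under 0.05, and 1036 genes did not overlap (5.69%, against 2.86% by chance). The count was 0 without unprimed replicate 3 or 4 or mesenchyme-primed replicate 2 or 3. It was 1 without glia-primed replicate 1 or 3 or neuron-primed replicate 1 or 4, and 2 without unprimed replicate 1, glia-primed replicate 2 or 4, neuron-primed replicate 2 or mesenchyme-primed replicate 1. It was 1 with the Xist level or the Gapdh ratio as a covariate. Pmepa1 (adjusted p of 0.00108 to 0.2 over the alternatives) was lost without any of 4 single arrays, Sipa1l2 (0.0185 to 0.421) of 13, and Gpr17 (0.0279 to 0.421) and Gins2 (0.0289 to 0.463) of 14. The list count was 7 without mesenchyme-primed replicate 3.

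**Figure D2:**
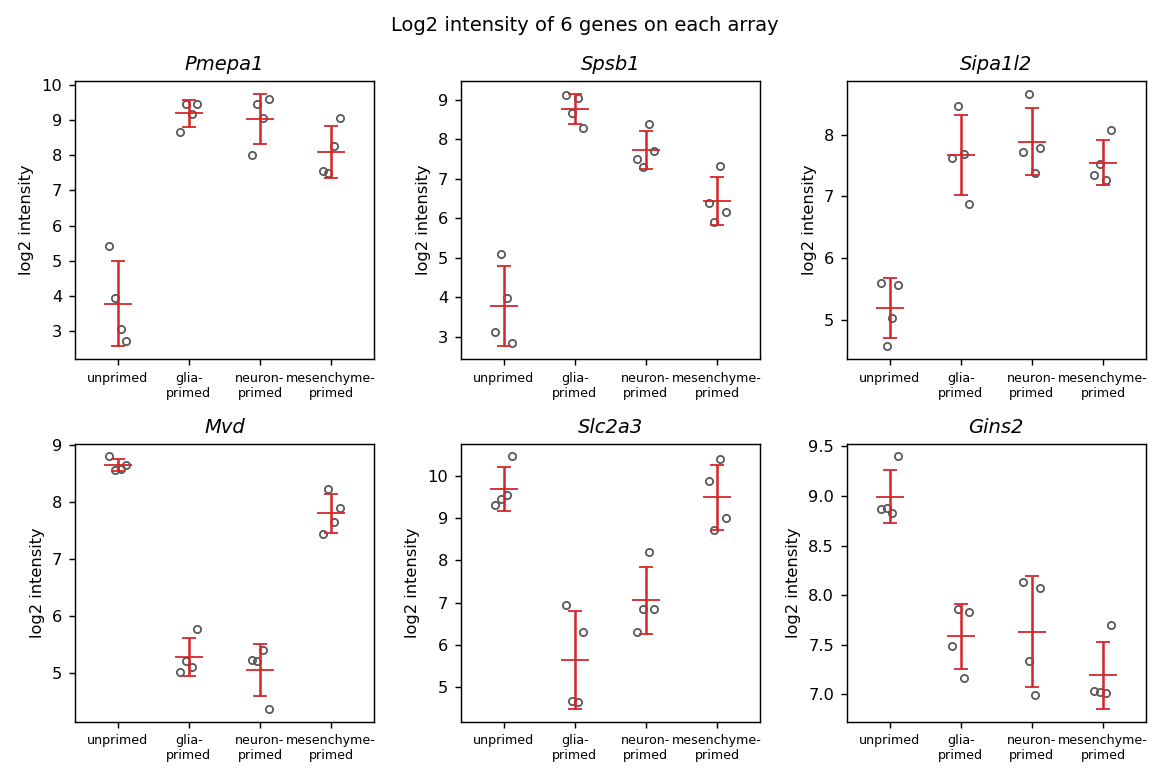
Log2 intensity on each of the 16 arrays of Pmepa1, Spsb1, Sipa1l2, Mvd, Slc2a3 and Gins2, with circles for arrays and red marks for the mean ± SD of 4 arrays; the panels have different vertical ranges. Pmepa1 lay at 3.78 in unprimed arrays on average and at 9.18, 9.03 and 8.09 in glia-, neuron- and mesenchyme-primed arrays.

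Pooling the primed groups asked what priming changes whatever its direction. Pmepa1 and Sipa1l2 were higher and Gins2 was lower in each primed group, which were the 3 genes changed in all of them, against 277 at an unadjusted p under 0.05 with the same sign. In the mean of the 3 primed groups against unprimed cells, 81 genes changed, 22 higher and 59 lower, with 21 and 46 at least 2-fold. Cholesterol synthesis genes had a median of -1.46, with 11 of 20 fallen and 20 when adjusted over the list alone (camera adjusted p = 3.18e-34, and adjusted p = 0.000735 with an estimated correlation). This pooled value came mainly from glia- and neuron-primed cells, where the list's mean changed by -2.39 (95% interval -2.80 to -1.97) and -2.18 (-2.59 to -1.77), against -0.28 (-0.69 to 0.13) in mesenchyme-primed cells. TGF-beta response genes had a median of 0.73 (camera adjusted p = 8.62e-08, and adjusted p = 0.00965 with an estimated correlation). Glia- and neuron-primed cells shared 12 of their higher and 25 of their lower genes, 0 genes went opposite ways, and independent lists of these sizes would share 0.0448 and 0.178. Both comparisons use the same unprimed arrays. With these split 2 and 2 between the comparisons, chosen after seeing the data, the 6 splits gave 3 to 4 shared higher and 4 to 6 shared lower genes, against at most 0.00462 and 0.0254 for independent lists of their sizes. Over all genes the log2 changes correlated at 0.644 for glia and neuron, 0.542 for glia and mesenchyme and 0.489 for neuron and mesenchyme, against 0.502, 0.502 and 0.501 in simulated unchanged groups that share the unprimed arrays. The covariances, also with shared unprimed arrays, were 0.213, 0.156 and 0.137 against 0.0883, 0.0881 and 0.088 simulated. With the unprimed arrays split between the comparisons the correlations were 0.323, 0.206 and 0.157. Genes are not independent replicates.

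The pooled count was 24, 27, 44 and 11 without unprimed replicates 1 to 4, 51, 36 and 41 without glia-primed replicates 1 to 3, 171 and 37 without neuron-primed replicates 1 and 4, and 33, 44 and 41 without mesenchyme-primed replicates 1 to 3. It was 6 with the Gapdh ratio as a covariate (5 of the 81 among them) and 39 with the Xist level (32 of the 81), both added after seeing the data. The count for all 3 groups was 0 without unprimed replicate 3 or 4 or mesenchyme-primed replicate 2 or 3, and 1 without glia-primed replicate 1 or 3, neuron-primed replicate 1, 3 or 4 or mesenchyme-primed replicate 1. Under housekeeping centring, which moved the median of all genes by 0.29, the pooled split was 24 higher and 9 lower, and under cyclic loess 20 and 23.

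Comparing primed groups asked which changes belong to a lineage. Mef2c was higher by 4.23 in glia-primed than in neuron-primed cells (adjusted p = 0.00119) and Vat1l was lower (log2 difference -2.76, adjusted p = 0.0101), the 2 genes that differed, against 1135 at an unadjusted p under 0.05. Against mesenchyme-primed cells, glia-primed cells had higher Cpm (3.61, adjusted p = 0.000854), Dhrs3, a retinaldehyde reductase (3.08, adjusted p = 0.00195), and Chst15 (2.46, adjusted p = 0.0307), and lower Slc2a3 (-3.85, adjusted p = 0.00917), Lss (-3.34, adjusted p = 0.00803) and Dhcr7 (-3.31, adjusted p = 0.0163). Neuron-primed cells had higher Vgf (5.41, adjusted p = 0.00825), Cpm (3.50, adjusted p = 0.00145) and Mmp9 (3.30, adjusted p = 0.0209) than mesenchyme-primed cells, and lower Bnip3 (-4.95, adjusted p = 0.0114), Mef2c (-4.63, adjusted p = 0.000185) and Cers4 (-4.08, adjusted p = 0.0145). In list tests added after seeing the data, cholesterol synthesis genes were lower in glia-primed than in mesenchyme-primed cells (median -2.01, 10 of 20 lower, camera adjusted p = 1.86e-46, and adjusted p = 0.000159 with an estimated correlation). They were also lower in neuron-primed cells (median -1.84, 8 of 20 lower, camera adjusted p = 2.75e-37, and adjusted p = 0.000482 with an estimated correlation). Hypoxia-response genes were lower in glia-primed (median -0.91, camera adjusted p = 2.7e-16, and adjusted p = 0.000791 with an estimated correlation) and neuron-primed cells (median -0.93, camera adjusted p = 4.27e-16, and adjusted p = 0.000839 with an estimated correlation).

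Glia- and mesenchyme-primed cells differed in 41 genes, 13 higher and 28 lower, and neuron- and mesenchyme-primed cells in 63, 25 higher and 38 lower. Under housekeeping centring, which moved the median of all genes by 0.26, -0.12 and 0.37 for glia against mesenchyme, glia against neuron and neuron against mesenchyme, the splits were 24 and 16 for the first and 68 and 20 for the last. The count of 41 was 18 and 22 without glia-primed replicates 3 and 4, 68 without neuron-primed replicate 1, and 14, 25 and 21 without mesenchyme-primed replicates 1 to 3, and 21 with the Xist level as a covariate (19 of the 41 among them). The count of 63 was 141, 37 and 41 without neuron-primed replicates 1, 2 and 4, and 37 and 36 without mesenchyme-primed replicates 1 and 2, and 26 with only these groups fitted. Chst15 against mesenchyme-primed cells (adjusted p of 0.015 to 0.098 over the alternatives) and Mmp9 (0.00705 to 0.0816) were lost without any of 6 single arrays, and Dhcr7 (0.00295 to 0.065) and Cers4 (0.00214 to 0.0569) of 3. The count of 2 was 5 without glia-primed replicate 1 and 7 and 4 without neuron-primed replicates 1 and 2.

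Genes higher in a primed group than in each other group numbered 0 for glia by limma, where 85 had unadjusted p-values under 0.05, 1 for neuron, where 120 did, and 1 for mesenchyme, where 81 did. Vat1l was the neuron-primed gene (1.79 against unprimed, SE 0.34, adjusted p = 0.0333, and 2.65 against mesenchyme-primed, adjusted p = 0.00371), and Gpr17 was the mesenchyme-primed gene. The count for glia was 1 without neuron-primed replicate 3. The count for neuron was 4 without neuron-primed replicate 1 and 0 without any unprimed replicate, neuron-primed replicate 3 or 4 or mesenchyme-primed replicate 1 or 4. The count for mesenchyme was 0 without any array other than neuron-primed replicate 3 or mesenchyme-primed replicate 1.

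**Figure D3:**
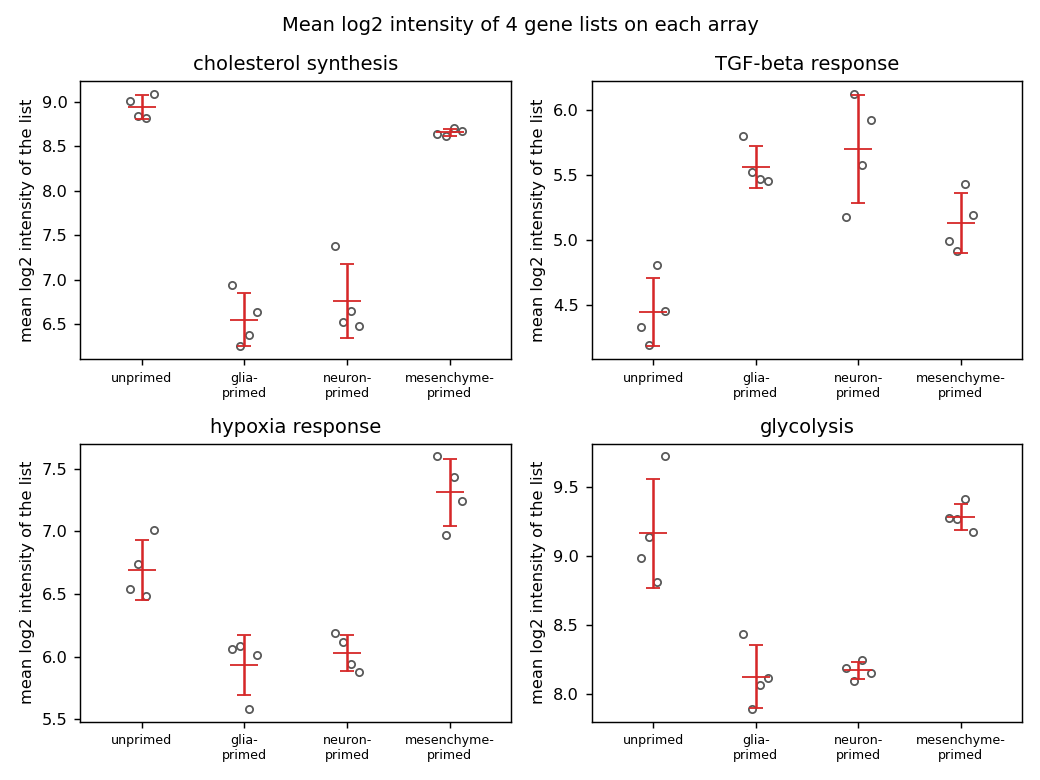
Mean log2 intensity on each of the 16 arrays of the genes of cholesterol synthesis, the TGF-beta response, the hypoxia response and glycolysis, with the mean ± SD of 4 arrays. Cholesterol synthesis genes averaged 8.94 in unprimed, 6.55 in glia-primed, 6.76 in neuron-primed and 8.66 in mesenchyme-primed arrays.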

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

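The tests of RNA quality and of a mesenchyme-primed array under a wrong label, the reading of unprimed arrays on the latter's score and that of cholesterol synthesis genes in this array were chosen after the result was seen. Within each group of 4 arrays, the gap of the highest or lowest array to its nearest neighbour was divided by the range of the group. Of 312 groups tested over named genes, lists and the first principal component, 23 lay beyond Dixon's bound, where chance gives about 5 percent. Unprimed replicate 4 accounts for 6 of them and neuron-primed replicate 1 for 3.

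Neuron-primed replicate 1 lay apart from its group in Sox10 (4.30 against a mean of 8.20, ratio 0.95), in general neuronal genes (5.70 against 4.87, ratio 0.914) and in sensory neuron genes (4.36 against 3.12, ratio 0.923), and it lay with the unprimed arrays on the first principal component. A mesenchyme-primed or unprimed array under a wrong label is argued against, since cholesterol synthesis genes averaged 7.38 in it, against 8.61 to 8.70 in mesenchyme-primed and 8.81 to 9.09 in unprimed arrays, and since on 141 genes separating the other neuron-primed from mesenchyme-primed arrays it scored 0.374, narrowly beyond 3 SD of left-out mesenchyme-primed (0.042 to 0.179, SD 0.0606) and unprimed arrays (0.033 to 0.172, SD 0.0581). On 166 genes separating glia-primed from unprimed arrays it scored 0.375, inside the mesenchyme-primed range of 0.327 to 0.403 but beyond the unprimed range of -0.114 to 0.064 (SD 0.079) by the bound set beforehand, although unprimed arrays left out of the fit reached 0.236 (SD 0.133), a spread that alone would leave it open. Its own group lay apart from it too. Neuron-primed replicates 2 to 4 scored 0.752 to 0.873 on the 141 genes when left out, and 0.883 to 0.899 on the 166 genes. Their cholesterol synthesis genes averaged 6.48 to 6.65. These values therefore do not place the array with its own group either. RNA quality stays open, but the ratios measured give no sign of degraded RNA in this array. Its beta-actin 3' to 5' log2 ratio of -0.918 lay below the other arrays (-0.701 to -0.074), while degradation raises this ratio, and its Gapdh ratio of 3.10 lay inside theirs (2.20 to 3.33). The rule written for this test counted a ratio outside the range on either side, and its reading was changed to open after the result was seen. Fewer neural crest cells in the sample is left open too. Crest genes had a median difference of -0.427 from the other neuron-primed arrays, but 17 of 27 were lower (exact sign test p = 0.248, two-sided), and the tests do not decide. Larger median differences, read after the result was seen, included smooth muscle (-1.395, 22 of 26 lower), matrix (-1.235, 24 of 33 lower) and Hox genes (1.163, 8 of 23 lower). Crest genes were therefore not what set this array apart most.

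In unprimed replicate 4, Rassf4 was highest (2.55 against 2.10, ratio 0.888), as were Gins2 (9.40 against 8.86, ratio 0.913), melanocyte genes (2.54 against 2.23, ratio 0.919) and mitotic genes (7.56 against 7.32, ratio 0.872). Mef2c (6.18 against 7.53, ratio 0.891) and Mycn (8.61 against 9.27, ratio 0.86) were lowest there. In glia-primed replicate 1, Rassf4 was lowest (4.05 against 7.26, ratio 0.848) and smooth muscle genes were highest (6.69 against 6.45, ratio 0.859). In glia-primed replicate 3, cell cycle exit genes were highest (5.80 against 5.33, ratio 0.895) and hypoxia-response genes lowest (5.58 against 6.05, ratio 0.861). In glia-primed replicate 4, Wnt pathway genes were highest (5.11 against 4.69, ratio 0.842), as was the first principal component (46.5, ratio 0.884). In neuron-primed replicate 3, Yy1 was highest (8.78 against 8.38, ratio 0.846). In neuron-primed replicate 4, Rassf4 was lowest (2.55 against 4.91, ratio 0.839) and erythroid genes were highest (4.41 against 2.97, ratio 0.978). In mesenchyme-primed replicate 2, Chst15 was lowest (2.86 against 4.51, ratio 0.873). In mesenchyme-primed replicate 3, Col1a2 (11.45 against 10.36, ratio 0.877) and Cers4 (8.54 against 7.31, ratio 0.854) were highest. In mesenchyme-primed replicate 4, Gins2 (7.70 against 7.02, ratio 0.958) and oxidative phosphorylation genes (9.02 against 8.88, ratio 0.979) were highest.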

How the results depend on the processing

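The offset of 16, the Xist level and the Gapdh ratio as covariates were chosen after the data were seen. Of 61 calls of named genes, 19 held in each setting, 32 held without each array and 1 reversed, and of 55 list calls 14 held in each setting and 2 reversed. Cholesterol synthesis, glycolysis, DNA replication and TGF-beta response lists held in each setting in glia-primed, neuron-primed and pooled arrays. Signal over background was not measured here, so levels near the array medians are not shown to exceed it. The cause was not tested unless fewer genes or arrays in a setting give it.

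Without each array, gene counts ranged from 25 to 168 (glia), 31 to 237 (neuron), 0 to 3 (mesenchyme), 11 to 171 (pooled), 2 to 7 (glia against neuron), 14 to 68 (glia against mesenchyme), 36 to 141 (neuron against mesenchyme), 0 to 3 (all 3), 0 to 1 (glia alone), 0 to 4 (neuron alone) and 0 to 1 (mesenchyme alone). List counts ranged from 12 to 14, 10 to 17, 7 to 14 and 13 to 15 for glia, neuron, mesenchyme and pooled.

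With the replicate number as a block the counts were 52 for glia, 39 pooled and 22 for glia against mesenchyme, and no other count of calls moved by over 1.5 times. Same-numbered arrays did not deviate together (correlations -0.081 to 0.07, median -0.005, 0 of 24 over 0.1, own number best in 5 of 24), so the numbers give no pairing.

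Median centring gave 1 gene for mesenchyme, 1 for all 3 and 0 for mesenchyme alone. Cyclic loess gave 43 genes and 9 lists pooled, and oxidative phosphorylation genes pooled turned to 0.025. Housekeeping centring gave 2 for mesenchyme, 33 pooled and 0 for mesenchyme alone. Leaving out the lowest 30 percent of genes gave 7 lists for mesenchyme. Leaving out the lowest 50 percent gave 0 genes for mesenchyme alone and 9 lists each for neuron and pooled, turned the test direction of endothelial genes in mesenchyme with the median at -0.273, and left too few melanocyte genes to test. Without cross-matching probe sets Cfap410 in neuron turned to 0.04. Testing every probe set gave 124 for neuron, 0 for mesenchyme, 5 for glia against neuron, 0 for all 3 and 0 for mesenchyme alone.

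eBayes with trend and robust gave 1 for mesenchyme, 1 for all 3, 0 for neuron alone and 0 for mesenchyme alone. Array weights gave 149 for glia, 9 for mesenchyme, 136 pooled, 62 for glia against mesenchyme and 5 for all 3. Treat at 1.2-fold gave 32 for glia, 35 for neuron, 1 for mesenchyme, 18 pooled, 21 for glia against mesenchyme, 33 for neuron against mesenchyme, 1 for all 3, 0 for neuron alone and 0 for mesenchyme alone. An estimated correlation gave 5, 4, 0 and 5 lists for glia, neuron, mesenchyme and pooled. The offset of 16 gave 0 for mesenchyme, 0 for all 3, 2 for neuron alone and 0 for mesenchyme alone. Xist as a covariate gave 26 for glia, 1 for mesenchyme, 39 pooled, 21 for glia against mesenchyme, 1 for all 3 and 0 for mesenchyme alone. The Gapdh ratio as a covariate gave 30 for glia, 33 for neuron, 1 for mesenchyme, 6 pooled, 1 for all 3, 0 for neuron alone, 0 for mesenchyme alone and 9 lists each for neuron and pooled. Fitting only the groups compared, with fewer arrays for the spread, gave 60 for glia, 17 for neuron, 0 for mesenchyme, 0 for glia against neuron and 26 for neuron against mesenchyme.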

Other observations

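The tests of the sex of the embryos, of array quality and of scaling that depends on intensity were chosen after the result was seen. In glia-primed arrays, ribosomal protein genes were lower as a list (median -0.21, camera adjusted p = 9.45e-06, and adjusted p = 0.176 with an estimated correlation), as were ribosome biogenesis genes (median -0.26, camera adjusted p = 0.00152, and adjusted p = 0.499 with an estimated correlation). Chromatin regulators were lower in glia-primed (median -0.30, camera adjusted p = 0.00581, and adjusted p = 0.0935 with an estimated correlation) and neuron-primed arrays (median -0.18, camera adjusted p = 0.00741, and adjusted p = 0.0971 with an estimated correlation), though in glia-primed arrays the adjusted p was 0.0539 without replicate 1. Under centring on housekeeping genes all genes moved by 0.33 in glia-primed and 0.44 in neuron-primed arrays, which put these medians at 0.127, 0.075, 0.033 and 0.263. Camera then did not call the ribosomal protein list (adjusted p = 0.261) and called the others (0.0104, 0.0124 and 0.0191). This centring leaves each list's log2 change relative to other genes as it was. Under cyclic loess none of these calls held, with medians of -0.098, -0.121, -0.159 and -0.038 (camera adjusted p = 0.059, 0.195, 0.195 and 0.159). Stress response genes were higher in neuron-primed than in mesenchyme-primed arrays (median 0.50, 2 of 22 higher, camera adjusted p = 8.01e-06, and adjusted p = 0.0271 with an estimated correlation). In that comparison glycolysis genes were lower (median -0.87, 5 of 19 lower, camera adjusted p = 2.3e-19, and adjusted p = 0.00165 with an estimated correlation).

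Cholesterol synthesis genes were lower in glia-primed and neuron-primed arrays. Scaling of the arrays is argued against, since the median nearest 0 over 3 scalings was -1.535, as is a single array, where it was -1.825 with any array left out. For neuron-primed arrays the sex of the embryos is argued against too. There the value nearest 0 of the fit with Xist as a covariate and the fit without replicate 1 was -1.917. For glia-primed arrays that test cannot tell, because their Xist levels (2.61 to 5.34) lay wholly below the unprimed ones (6.39 to 10.5). A candidate explanation is lower SREBP activity, because 17 other SREBP targets changed by -0.79 in glia-primed (95% interval -1.07 to -0.503) and by -0.81 in neuron-primed arrays (-1.09 to -0.52). Whether a sterol surplus lies behind it is open, as 10 LXR targets, which sterols induce, changed by 0.20 (-0.164 to 0.57) and 0.36 (-0.01 to 0.72). Array quality as the Gapdh ratio measures it is argued against, as the median nearest 0 was -2.024 with that ratio as a covariate and mesenchyme-primed arrays, with a like ratio of 2.96, averaged 8.66 for these genes against 6.55 and 6.76, while the growth factor conditions moved with the groups and stay open.

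Hypoxia-response genes were higher in mesenchyme-primed arrays and lower in glia- and neuron-primed arrays, and the list's mean differed by 1.33 between the first and the mean of the others, although against unprimed arrays each call was lost (adjusted p = 0.178, 0.0633 and 0.0717 with an estimated correlation for mesenchyme, glia and neuron). A single array is argued against, since the difference was at least 1.233 with any array left out. Scaling that depends on intensity is argued against, since relative to all genes the medians of mesenchyme- and neuron-primed arrays differed by 0.861 under cyclic loess. A scaling that moves all genes of an array alike leaves the list relative to other genes as it is and bears on the level alone, whose difference went from 0.758 as deposited to 0.399 under housekeeping centring, which moved all genes by 0.37. The value of 0.399 fell just short of the bound set beforehand, so the scaling test cannot tell for the level. The housekeeping genes fixed for it include Gapdh and Pgk1 of the glycolysis list. That list's mean was also lower in neuron- than in mesenchyme-primed arrays (difference -1.11), so this centring may itself take up part of the difference tested. A wider oxygen response may account for the pattern, because 21 other hypoxia-induced genes differed by 0.39 (95% interval 0.235 to 0.55), and the oxygen or density of the cultures is not given in the sources used here.

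Splits of the same arrays into groups of these sizes tested whether chance could give such counts. The splits counted, 35 or 100, include the real grouping itself. For glia against unprimed 1 of 35 splits gave as many genes (93, highest other 1), for neuron 1 of 35 (79, highest other 4) and for mesenchyme 1 of 35 (4, highest other 1). Between primed groups it was 1 of 35 for glia against neuron (2, highest other 1), 1 of 35 for glia against mesenchyme (41, highest other 2) and 1 of 35 for neuron against mesenchyme (63, highest other 5). Of 100 splits, 1 gave as many pooled genes (81, highest other 2), 1 as many in all 3 groups (3, highest other 1), 1 as many for neuron alone (1, highest other 0) and 3 as many for mesenchyme alone (1, highest other 1). For the counts of 41 or more no other split came near, which argues against chance but does not exclude it. The shares are not adjusted for the number of counts tested, and with 35 splits 1 of 35 is the smallest share possible. A split that mixes the groups also puts their differences into the spread, which lowers its own count. For the counts of 1 to 4 and the pooled lists (2 of 100, 14 lists, highest other 14) the shares are under 0.05 too. The same limits hold for these, and they lie within 3 of the highest other, so chance is not firmly excluded for them. The count of 0 for glia alone cannot be tested this way, because every split reaches at least 0 (100 of 100, highest other 1). Chance is not excluded for the number of lists in glia (3 of 35, 14 lists, highest other 15), neuron (4 of 35, 15 lists, highest other 18) or mesenchyme (2 of 35, 12 lists, highest other 13).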
